A study of Neurospora crassa with 6 samples.

How the data were processed

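Poly(A) RNA of Neurospora crassa wild-type cultures was sequenced as single reads of 50 bp, per the labels' protocols. The 6 libraries, 1 per group, cross staurosporine at 20 µM or DMSO with 3 media (standard, 0 Ca2+ and 20 mM CaCl2). Reads were aligned with TopHat2 2.0.4 and quantified and compared with Cufflinks 2.0.2 and Cuffdiff, per the submitters' processing notes. The genome build and annotation are not given in the sources used here. The data come as 5 tables of 9691 genes each, 1 for each comparison of 2 libraries. Per the file headers, each table holds the authors' FPKM of both libraries, their log2 ratio, and p and q values with a yes or no call of significance. FPKM divides fragments by transcript length and library size, so it is relative to the rest of its library. A library that stands in more than 1 table had identical FPKM in each, with 0 of 9691 genes differing, so values were compared across tables. The p and q values in the authors' deposited table come from single libraries and are given only as the authors' calls. Library columns were assigned to groups by their names, the standard medium being named as minimal medium.

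The tables hold no read counts and the depth of each library is unknown, so no interval for counting error is given. Low FPKM values showed repeated steps that could be matched only between DMSO libraries. There the commonest ratio of low values to the standard library was 0.8 for 0 Ca2+ (21 of 319 genes) and 0.54 for 20 mM CaCl2 medium (15 of 338). The next were 0.89 (14 genes) and 0.64 (10 genes), so the match is weak, and it fixes no absolute depth. An FPKM of 0 can be a failed estimate, and such a gene is said to be listed at 0. Gene symbols and products were taken from the tables and from a RefSeq gene table of assembly NC12, matched by locus tag for 9141 IDs; 4617 IDs had a symbol or an informative product. That table gave gene neighbours and gene lengths but no strand, and no coordinates are reported because the build of the tables is not known. Of the IDs, 66 name 2 or more loci.

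Comparisons used log2((FPKM + 1) ratio), which understates the change of low genes. Within 1 comparison there is no replicate and no test: genes with a mean FPKM of at least 1 over the libraries compared were counted as higher or lower when the absolute log2 ratio was at least 1. The effect of staurosporine over the media was tested with limma 3.58.1 in R 4.3.3 (moderated test with a mean trend, two-sided) on the 3 within-medium ratios of 7415 genes against 0, taking the 3 media as repeats, with a Benjamini-Hochberg adjusted p below 0.05 and an absolute mean log2 ratio of at least 1. Each SE given is limma's moderated standard error, for which a gene's variance is drawn toward that of genes of similar level. It can be smaller than the plain standard error over the 3 media. The moderated test was tested on simulated data with 100 genes changed at each of 2 sizes among 7415. With a median sample SD of 0.31 over the 3 simulated ratios of a gene, 87% were recovered at a log2 ratio of 1.5 and 98% at 3, with 0 false calls. With spreads drawn from the distribution fitted to the real ratios (median of the SDs drawn 0.75, not a sample SD), 2% and 70% were recovered with 2 false calls, so the test misses most changes of the smaller size. Genes were simulated as independent, so the numbers of false calls do not carry over to genes that move together. Gene sets were 28 lists defined by symbol or product patterns. Lists of at least 5 genes were tested over the media with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Within 1 comparison a list's median was placed among the medians of 10000 random lists of equal size matched on mean FPKM in 20 bins. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.

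Groups, tests, size rules, lists, the rule for named genes and all alternatives but 3 were chosen before the data were examined. Genes named are the 8 highest and 8 lowest ratios with a symbol or informative product in each comparison of libraries, the 4 at each end for differences between media, those past the test over the media, the 2 at each end of all genes by ID, up to 4 members with the largest ratio in each list described, and NCU09974 with NCU09975. The alternatives were pseudocounts of 0.1 and 5, no filter, a minimum mean FPKM of 10, ratios centred on the median of genes with FPKM of at least 10, FPKM rescaled to sum to 1000000, the authors' testable genes alone, an unpaired fit, leaving out 1 medium, and no minimum fold. Added after the data were seen were removal of the trend with gene length, for the 7068 genes with a length (95.3%), and, for the gene lists, no filter and the authors' testable genes alone.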

Results

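The transcriptomes of 6 cultures of the filamentous fungus Neurospora crassa were measured by RNA sequencing on poly(A) RNA. Wild-type conidia, the asexual spores, were germinated for 6 h and then kept for 1 h with staurosporine at 20 µM, a protein kinase inhibitor that induces cell death in this fungus, or with its solvent DMSO. Each treatment was applied in standard minimal medium, in a medium labelled 0 Ca2+ and in a medium with 20 mM CaCl2, which gives 6 groups of 1 library each. The study asked how the response to staurosporine depends on external calcium. No group has a second library, so no value within 1 medium has a replicate error. FPKM values summed to 940589.8, 953522 and 1001098 in the DMSO libraries of the standard, 0 Ca2+ and 20 mM CaCl2 media, and to 500315, 696047 and 666121 in the staurosporine libraries. Read depth is unknown. Across genes, the standard DMSO library correlated at r = 0.978 and 0.986 with the other DMSO libraries, and the 0 Ca2+ staurosporine library stood farthest from the rest, at r = 0.734 with the 20 mM staurosporine library. These correlations are across genes, which are not independent replicates.

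Taken over the 3 media as repeats, staurosporine raised a small set of genes with large ratios. NCU09975, an ABC drug transporter gene known as abc-3, rose by a mean log2 ratio of 5.70 (moderated SE 0.58, as for each SE below). Its chromosomal neighbour NCU09974, the zinc cluster transcription factor gene known as czt-1, rose by 4.06 (SE 0.43). FPKM of NCU09975 went from 5.95 to 699.9 in standard medium, from 9.31 to 158 in 0 Ca2+ medium and from 5.55 to 593 in 20 mM CaCl2 medium. The pyridoxal reductase gene mig-9, of vitamin B6 metabolism, rose by 5.65 (SE 0.45) and reached 6673 FPKM in 20 mM CaCl2 medium. The cytochrome P450 gene NCU09115 rose by 4.10 (SE 0.39). Among genes without a name, NCU04287 rose by 4.91 (SE 0.46) and NCU09140, which lies next to mig-9, by 3.79 (SE 0.36). The named genes that fell were cfp, encoding the pyruvate decarboxylase of ethanol fermentation, with a mean log2 ratio of -3.36 (SE 0.39), and the UDP-glucose dehydrogenase gene NCU08228, with -3.15 (SE 0.37). NCU11843, NCU01871, NCU06940 and NCU07352, all of unknown product, fell with mean log2 ratios of -4.33 (SE 0.34), -3.81 (SE 0.45), -3.76 (SE 0.42) and -3.38 (SE 0.38).

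In limma's moderated test 12 of 7415 genes passed, 6 higher and 6 lower, all in the same direction in 3 of 3 media, and 1047 genes had an unadjusted p below 0.05. Adjusted p was 0.0419 for NCU09975, 0.0471 for NCU09974, 0.0252 for mig-9, 0.0351 for NCU09115, 0.0351 for NCU04287 and 0.04995, just under the threshold, for cfp. All 6 libraries enter this test as 3 pairs, so its spread holds library noise and any dependence on the medium. The count rested on single pairs and on settings. It was 0 without the standard pair, 15 higher and 20 lower without the 0 Ca2+ pair, and 174 higher and 362 lower without the 20 mM pair. It was also 0 with ratios centred on their median, with a pseudocount of 5, with no filter and with the gene length trend removed.

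**Figure D1:**
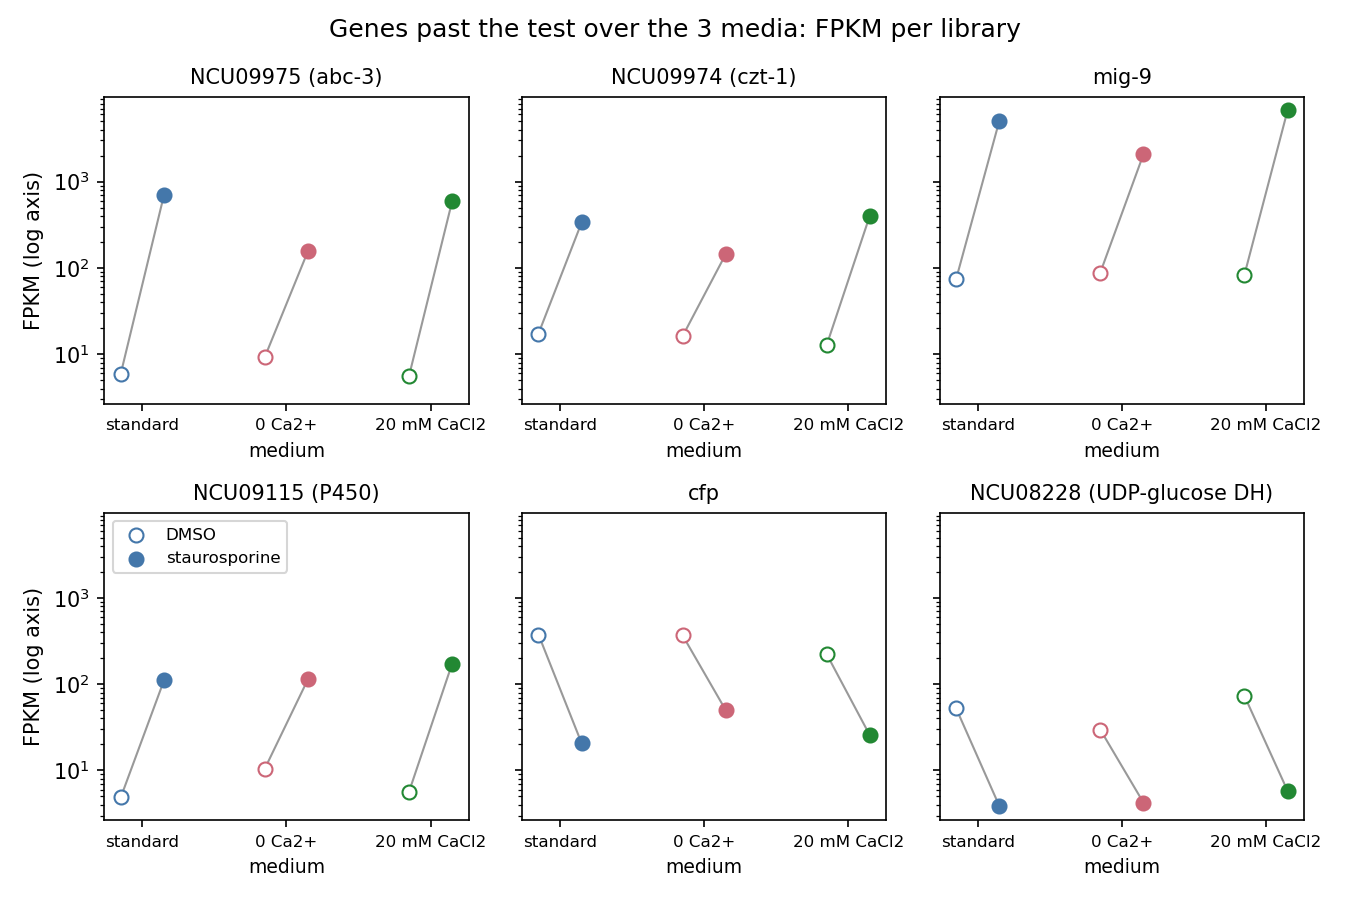
FPKM on a log axis for 6 genes that passed the test over the 3 media, by medium; open points are DMSO libraries, filled points staurosporine libraries, 1 library each, and lines join the pair of a medium. NCU09975, NCU09974, mig-9 and NCU09115 lay higher with staurosporine in each medium, and cfp and NCU08228 lower.

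Ribosomal protein genes stood lower as groups. Over the 3 media the 80 cytosolic ribosomal protein genes had a median of their mean log2 ratios of -1.17, and 71 of them were lower in every medium. Adjusted over the list alone, 39 of the 80 fell, and 0 passed over all genes. The 23 mitochondrial ribosomal protein genes had a median of -1.22, with 16 falling when adjusted over the list alone and 0 over all genes, among them NCU08120 (DAP3) at -1.94 (SE 0.40) and NCU05717 (Mrp17) at -1.77 (SE 0.33). In the camera test with a preset correlation of 0.01, 9 of 27 lists passed, but with an estimated correlation none did, and the adjusted p of these 9 then lay between 0.614 and 0.688. The estimate was 0.691 for cytosolic ribosomal proteins and 0.949 for ribosome biogenesis, so the p values that follow hold only for the preset value. Those lower than other genes were cytosolic ribosomal proteins (adjusted p = 1.69e-23), mitochondrial ribosomal proteins (8.75e-12), ribosome biogenesis (2.99e-12), amino acid synthesis (2.82e-05), respiratory complexes III to V (5.91e-05), complex I (5.25e-04) and nitrogen use (0.00597). Those higher were cell wall genes (0.0361) and conidiation genes, here called conidia markers (0.0271), of which con-10 passed when adjusted over the list alone. The conidia markers were matched on symbols such as con, eas and fl and on products naming conidiation or hydrophobin. They do not measure how many spores stayed ungerminated. Cell wall genes did not pass with the authors' testable genes alone (0.0985) or with a mean FPKM of at least 10 (0.0587), and the conidia markers not with a pseudocount of 5 (0.0537) or equal FPKM sums (0.0525). Complex I did not pass with equal sums (0.0563) and nitrogen use not with a mean FPKM of at least 10 (0.0517). With equal FPKM sums the medians turned positive for amino acid synthesis in standard and 20 mM CaCl2 medium (0.41 and 0.13), for complex I in standard and 0 Ca2+ medium (0.48 and 0.16) and for nitrogen use in the same 2 media (0.15 and 0.077). Those of complexes III to V turned positive in 0 Ca2+ and 20 mM CaCl2 medium (0.38 and 0.045), while the medians of both ribosomal protein lists stayed below 0 in every medium. The camera test does not match genes on level. Among random lists matched on level, complexes III to V lay at percentiles 1.6, 97.1 and 27.6 in standard, 0 Ca2+ and 20 mM CaCl2 medium. In that order complex I lay at 10.2, 47.6 and 0. Amino acid synthesis lay at 5.16, 0.2 and 13.0, and nitrogen use at 0.59, 23.7 and 0. Cell wall genes lay at 98.6, 62.2 and 100, with a median of -0.024 in 0 Ca2+ medium. Of 78 cell wall genes, 19 had ratios above 0 in all 3 media and 14 below 0. Ribosome biogenesis did not go one way over the media: 8 of 50 genes were lower in 3 of 3 media, and the median in 20 mM CaCl2 medium was 0.43, with 42 of 50 above 0. Genes of the sexual development and mating list had medians of 0.28, 0.18 and 0.08 in standard, 0 Ca2+ and 20 mM CaCl2 medium.

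In standard medium nearly all cytosolic ribosomal protein genes were lower with staurosporine, and the resistance pair NCU09974 and NCU09975 was among the highest. The NADP-dependent malic enzyme gene NCU03651 was at 68.3 FPKM with DMSO and 1.69 with staurosporine, a log2 ratio of -4.69. The malate dehydrogenase gene NCU04122 was at -4.50, cfp at -4.13 and aod-1, which encodes the alternative oxidase that bypasses complexes III and IV, at -4.18. The flavohemoglobin gene NCU10051 (-4.12), nic-7 (-3.66), the catalase gene cat-3 (-3.62) and NCU08228 (-3.46) completed the 8 lowest named genes. At the other end, NCU09975 had a log2 ratio of 6.66, mig-9 6.08, the dihydroxyacetone kinase gene dak-1 4.36, NCU09115 4.25 and NCU09974 4.21. The fucose permease gene NCU05897 (4.10), the mitochondrial succinate/fumarate transporter gene NCU08561 (3.91) and the chitinase gene gh18-5 (3.80) followed. Of genes without a name, NCU04287 was among the highest at 6.09; NCU04276 went from 387 to 3.31 FPKM, and NCU01579 from 106 FPKM to being listed at 0.

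Of the 80 cytosolic ribosomal protein genes, 75 were lower by at least 2 times and 0 higher, with a median log2 ratio of -2.10 (quartiles -2.24 and -1.86), at percentile 0 of 10000 random lists matched on level. NCU05599 (ribosomal protein S28) went from 3677 to 567 FPKM and NCU07562 (L43) from 8606 to 1603. Of 50 ribosome biogenesis genes 45 were lower by at least 2 times (median -1.59), of 23 mitochondrial ribosomal protein genes 20 (median -1.54), and of 28 genes of respiratory complexes III to V 20 (median -1.13), among them qcr8 at -1.68. Of 29 calcium handling genes 11 were higher by at least 2 times and 0 lower, at a median of 0.27 and percentile 87.0, short of the outer 2.5% of random lists, and the list did not pass the camera test over the media (adjusted p = 0.390). The calcineurin binding protein gene NCU01504 went from 63.7 to 430.3 FPKM, the P-type ATPase gene ena-1 from 35.1 to 152 and cax, the vacuolar calcium/proton exchanger, from 12.4 to 37.9. The gene ena-1 is in this list by its annotated product alone, which does not settle the ion it moves. The conidiation genes of the conidia marker list were higher too, with a median of 1.02 over 10 genes at percentile 99.7. Of them 5 were higher by at least 2 times, including con-10 from 1.11 to 7.14 FPKM. Of ABC transporter genes 7 of 17 were higher and 2 lower by at least 2 times, at a median of 0.75 and percentile 99.6.

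In all, 958 of 7167 genes were higher and 1071 lower by at least 2 times on the FPKM + 1 scale; the authors' deposited table calls 920 genes higher and 1001 lower as significant. When each library was scaled to the same FPKM sum, all ratios shifted by a median of 0.87 and the split became 3500 higher and 367 lower. The medians of the ribosomal protein, biogenesis and complexes III to V lists kept their sign under that scaling (-1.19, -0.74 and -0.23).

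In 0 Ca2+ medium, ribosome biogenesis genes had the lowest median of the 28 lists in any of the 5 comparisons of libraries. All 50 genes of that list were lower by at least 2 times, with a median log2 ratio of -3.71 (quartiles -4.06 and -2.60), at percentile 0 of matched random lists. The nucleolar protein gene NCU03396 (nop-58) went from 178 to 5.11 FPKM, NCU09521 (ribosome biogenesis protein) from 54.1 to 0.856, and NCU02546 (nucleolar GTP-binding protein 2) had a log2 ratio of -4.52. Other low genes were the RNA helicase gene NCU01369 (ded-1), which went from 321 to 7.74 FPKM, NCU07839 (dbp-2), another RNA helicase gene, from 161 to 3.65, NCU05650, the karyopherin Kap123 that imports ribosomal proteins, from 77.0 to 1.33, fkr-4 from 162 to 4.42 and hsp70-2 from 2550.1 to 87.1. The log2 ratio of the malic enzyme gene NCU03651 was -5.03 and that of the phosphate transporter gene NCU07375 -4.90.

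The highest named ratio belonged to NCU09473, annotated as a 3-ketoacyl-acyl carrier protein reductase, which went from 24.3 to 3086 FPKM (log2 ratio 6.93). NCU04639 (Nce102, of the plasma membrane) followed at 4.65, then the peroxisomal copper amine oxidase gene NCU05518 (4.64), mig-9 (4.55), the thymine dioxygenase gene NCU06416 (4.38), NCU03682 (4.38), the norsolorinic acid reductase gene NCU07723 (4.37) and the agmatinase gene NCU11320 (4.24). NCU09975 and NCU09974 were at 3.94 and 3.09. Of genes without a name, NCU12134 went from 4.27 to 239 FPKM and NCU04276 from 553 to 4.39. Heat shock and chaperone genes had 25 of 50 members lower and 4 higher by at least 2 times (median -1.01), and amino acid synthesis genes 24 of 58 lower and 1 higher (median -0.76), among them aro-6 at -3.37 and cys-11, the sulfate adenylyltransferase gene, at -3.01. Cytosolic ribosomal protein genes had 19 of 80 lower and 0 higher by at least 2 times, at a median of -0.68. Among conidia markers con-10 went from 2.44 to 35.1 FPKM and con-6 from 2.47 to 42.2, and 4 of 10 were higher and 1 lower by at least 2 times.

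Over all genes 1409 of 7531 were higher and 1571 lower by at least 2 times; the authors' deposited table lists 1186 higher and 1563 lower as significant. Scaling to equal FPKM sums shifted the ratios by a median of 0.43 and gave 2212 higher and 1041 lower; the medians for ribosome biogenesis, chaperones, amino acid synthesis and ribosomal proteins were then -3.48, -0.59, -0.32 and -0.22.

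In 20 mM CaCl2 medium the size rule was met by fewer genes than in the other media, and the resistance pair was again among the highest. NCU09975, at 593 FPKM with staurosporine, mig-9 (log2 ratio 6.32), NCU09974 (4.89) and NCU09115 (4.72) led the named genes, followed by the monooxygenase gene NCU00955 (2.76), the MFS transporter gene NCU04656 (2.73), the RTA1 domain gene NCU02363 (2.66) and NCU09976 (2.38), a rhamnogalacturonan acetylesterase gene next to NCU09975. The lowest were fkr-3 (-3.55), NCU08228 (-3.45), cfp (-3.08), the MFS transporter gene NCU10368 (-2.76), the carotenoid synthesis genes al-2 (-2.67) and al-1 (-2.53), the dimethylaniline monooxygenase gene NCU10387 (-2.52) and the aminotransferase gene NCU11365 (-2.45). For al-1 and al-2 the DMSO library of this medium is the one in which both were higher than in standard medium (2.24 and 2.23), so these values share that library. Of genes without a name NCU11843 was lowest, at -4.10.

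Ribosome biogenesis genes lay on the other side of 0 here: 42 of 50 had a ratio above 0, 4 by at least 2 times, with a median of 0.43 at percentile 100. Kap123 (NCU05650) went from 77.5 to 167 FPKM and nop-58 (NCU03396) from 183 to 280.4. Cytosolic ribosomal protein genes had 19 of 80 lower by at least 2 times (median -0.80). Of 31 complex I genes, 31 had a ratio below 0 and 5 were lower by at least 2 times (median -0.81), with nuo20.9 from 284 to 124 FPKM. The DMSO library they are measured against held this list higher than standard medium (median 0.80), so 1 high library would give both values. Nitrogen use genes included nit-6, encoding nitrite reductase, at -2.42 and the glutamine synthetase gene gln-1 at -0.80, with 6 of 17 lower by at least 2 times (median -0.81). Conidia markers had 3 of 10 higher and 0 lower by at least 2 times, at a median of 0.06 and percentile 75.2. Calcium handling genes had 4 of 30 higher and 0 lower by at least 2 times, at a median of 0.20 and percentile 99.88. With staurosporine in 0 Ca2+ medium that list lay at percentile 19.15.

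The size rule counted 189 of 7204 genes higher and 444 lower, and the authors' deposited table calls 145 higher and 309 lower as significant. The balance depended on scaling: centring the ratios, a shift of 0.23, gave 393 higher and 230 lower, and equal FPKM sums, a shift of 0.55, gave 940 and 124. Under equal sums the medians of the ribosome biogenesis, ribosomal protein, complex I and nitrogen use lists were 1.01, -0.21, -0.23 and -0.29.

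**Figure D2:**
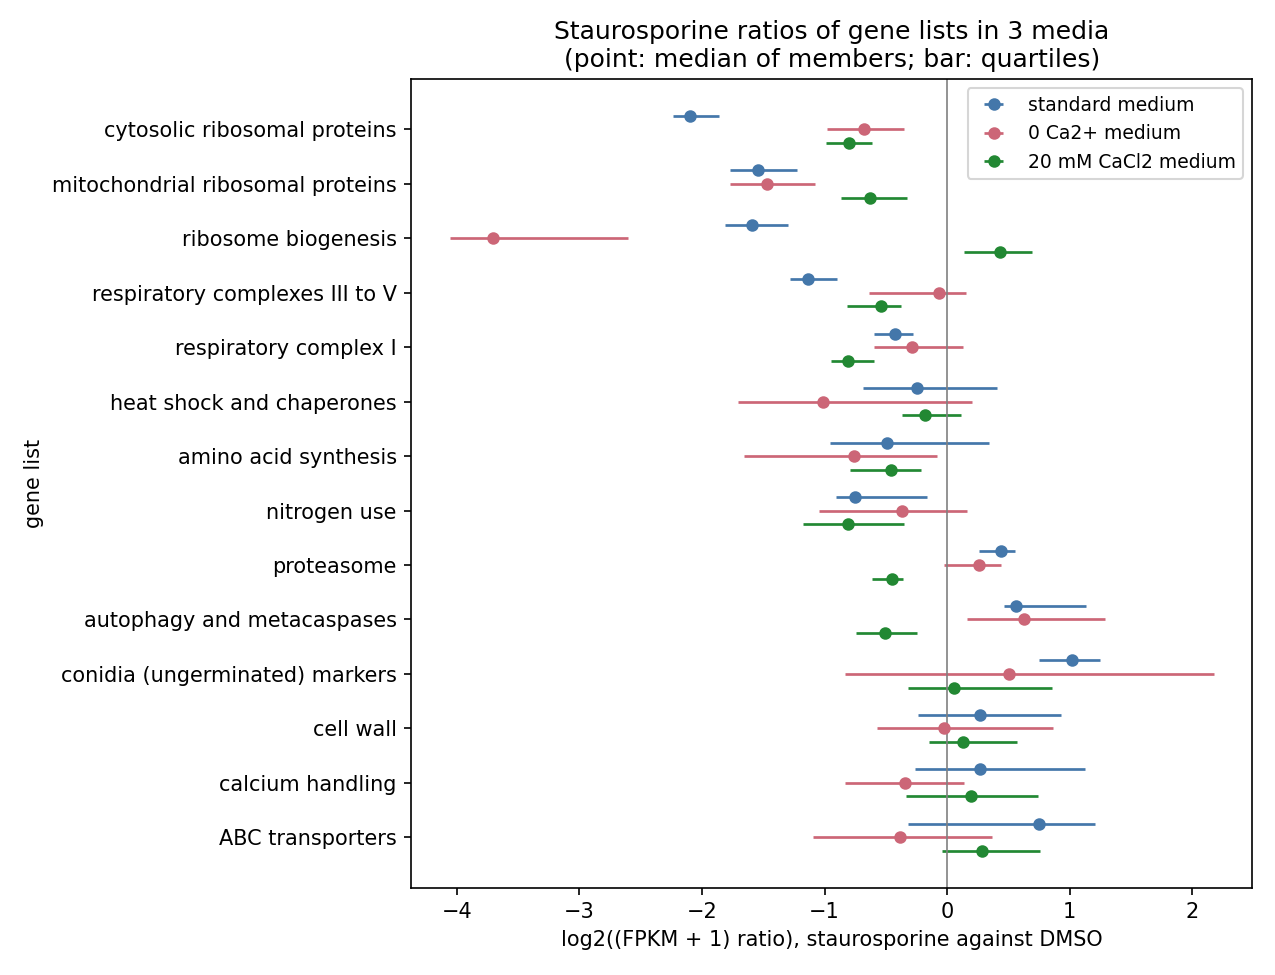
Log2((FPKM + 1) ratio) of staurosporine against DMSO for 14 gene lists in 3 media, 1 pair of libraries each; points are medians over list members and bars run between quartiles. Ribosome biogenesis had medians of -1.59, -3.71 and 0.43 in standard, 0 Ca2+ and 20 mM CaCl2 medium, and cytosolic ribosomal proteins -2.10, -0.68 and -0.80.

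Genes with large staurosporine ratios overlapped between the 0 Ca2+ and standard media and little between the 0 Ca2+ and 20 mM CaCl2 media. Of 7415 genes, 668 were lower by at least 2 times in both standard and 0 Ca2+ medium, against 229 for independent lists, and 420 were higher in both, against 163. For 0 Ca2+ and 20 mM CaCl2 medium these counts were 101 lower against 95.0 and 47 higher against 31.8, and 150 genes went opposite ways by at least 2 times. For standard and 20 mM CaCl2 medium, 190 were lower in both against 65.0, and 94 higher against 23.6. Across these genes the ratios of standard medium correlated at r = 0.543 with those of 0 Ca2+ medium and 0.379 with those of 20 mM CaCl2 medium, and those of 0 Ca2+ and 20 mM CaCl2 medium at -0.0679; genes are not independent replicates. In each of the 3 media, 35 genes were higher and 83 lower by at least 2 times, NCU09975, mig-9 and NCU09115 among the higher and cfp and NCU08228 among the lower.

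The staurosporine effect in 0 Ca2+ medium minus that in standard medium was at its lowest, among named genes, for gdh-1, the NAD-specific glutamate dehydrogenase gene, with log2 ratios of 2.56 in standard and -3.57 in 0 Ca2+ medium. With DMSO alone gdh-1 stood at a log2 ratio of 3.08 in 0 Ca2+ against standard medium, while the difference between the effects was -6.13. Part of a difference between effects can thus lie in the DMSO libraries, here as for the other genes and lists compared between media. The glucose transporter gene NCU05627 (ratios 1.75 and -2.91), the invertase gene inv (2.30 and -2.22) and the pentatricopeptide repeat gene NCU08674 (0.56 and -3.83) followed. It was at its highest for NCU03682 (difference 4.07), NCU10368 (3.60), set-6 (3.28) and NCU09473 (3.19). Ribosome biogenesis genes had a median difference of -2.17, with 39 of 50 at least 1 lower in 0 Ca2+ medium, and cytosolic ribosomal protein genes one of 1.33, with 59 of 80 at least 1 higher. For calcium handling genes it was -0.86, at percentile 0.44 of matched random lists, with 13 of 29 at least 1 lower. The calcineurin binding protein gene NCU01504 had ratios of 2.74 in standard and 0.54 in 0 Ca2+ medium. Differences of at least 1 were counted for 1130 genes above and 1604 below 0 of 7426, and with equal FPKM sums for 844 and 2653. That scaling shifted the ratios by a median of 0.87 in standard and 0.43 in 0 Ca2+ medium. It thus moves the differences downward, the 1.33 of the cytosolic ribosomal protein genes included.

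For 20 mM CaCl2 medium minus standard medium, the malic enzyme gene NCU03651 (4.75), the malate dehydrogenase gene NCU04122 (4.33), the plasma membrane fusion gene Prm1 (3.70) and cut-1 (3.25) had the highest differences among named genes. FPKM of NCU03651 was 35.8 with DMSO and 37.5 with staurosporine in 20 mM CaCl2 medium. The lowest were dak-1 (-4.91), the O-methyltransferase gene NCU02328 (-4.66), NCU09473 (-4.01) and NCU12074 (-3.84). Ribosome biogenesis genes had a median difference of 2.14 (47 of 50 at least 1 higher in 20 mM CaCl2 medium), cytosolic ribosomal protein genes 1.25 (56 of 80) and mitochondrial ribosomal protein genes 0.90 (8 of 23). In total 822 genes lay at least 1 above and 1130 at least 1 below 0 of 7214, with ratios centred 1049 and 752, and with equal FPKM sums 605 and 2044. Equal sums shifted the ratios by a median of 0.87 in standard and 0.55 in 20 mM CaCl2 medium. The positive median differences of the ribosomal lists thus become smaller under that scaling.

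Between 20 mM CaCl2 and 0 Ca2+ medium the effects differed by at least 1 for more genes than between the other media. Kap123 (NCU05650), the mitochondrial carrier gene NCU01916, dbp-2 (NCU07839) and the phosphate transporter gene NCU07375 had differences of 6.17, 5.84, 5.73 and 5.67. At the other end stood NCU09473 (-7.20), NCU06416 (-6.71), NCU05518 (-5.71) and the uracil-5-carboxylate decarboxylase gene NCU06417 (-5.28). FPKM of NCU06416 with DMSO was 3.14 in 0 Ca2+ and 48.8 in 20 mM CaCl2 medium and with staurosporine 85.3 and 8.91. Of 50 ribosome biogenesis genes 49 lay at least 1 higher in 20 mM CaCl2 medium (median difference 4.26, quartiles 2.91 and 4.88), and 21 of 50 chaperone genes did (median 0.75). For calcium handling genes the median difference was 0.67, at percentile 99.3, with 10 of 30 at least 1 higher and 2 lower. The counts over 7480 genes were 1536 at least 1 higher and 1745 at least 1 lower. With equal FPKM sums they were 1801 and 1725, in total close to the 844 and 2653 for 0 Ca2+ minus standard medium. With 1 library per group none of these differences between media was tested.

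**Figure D3:**
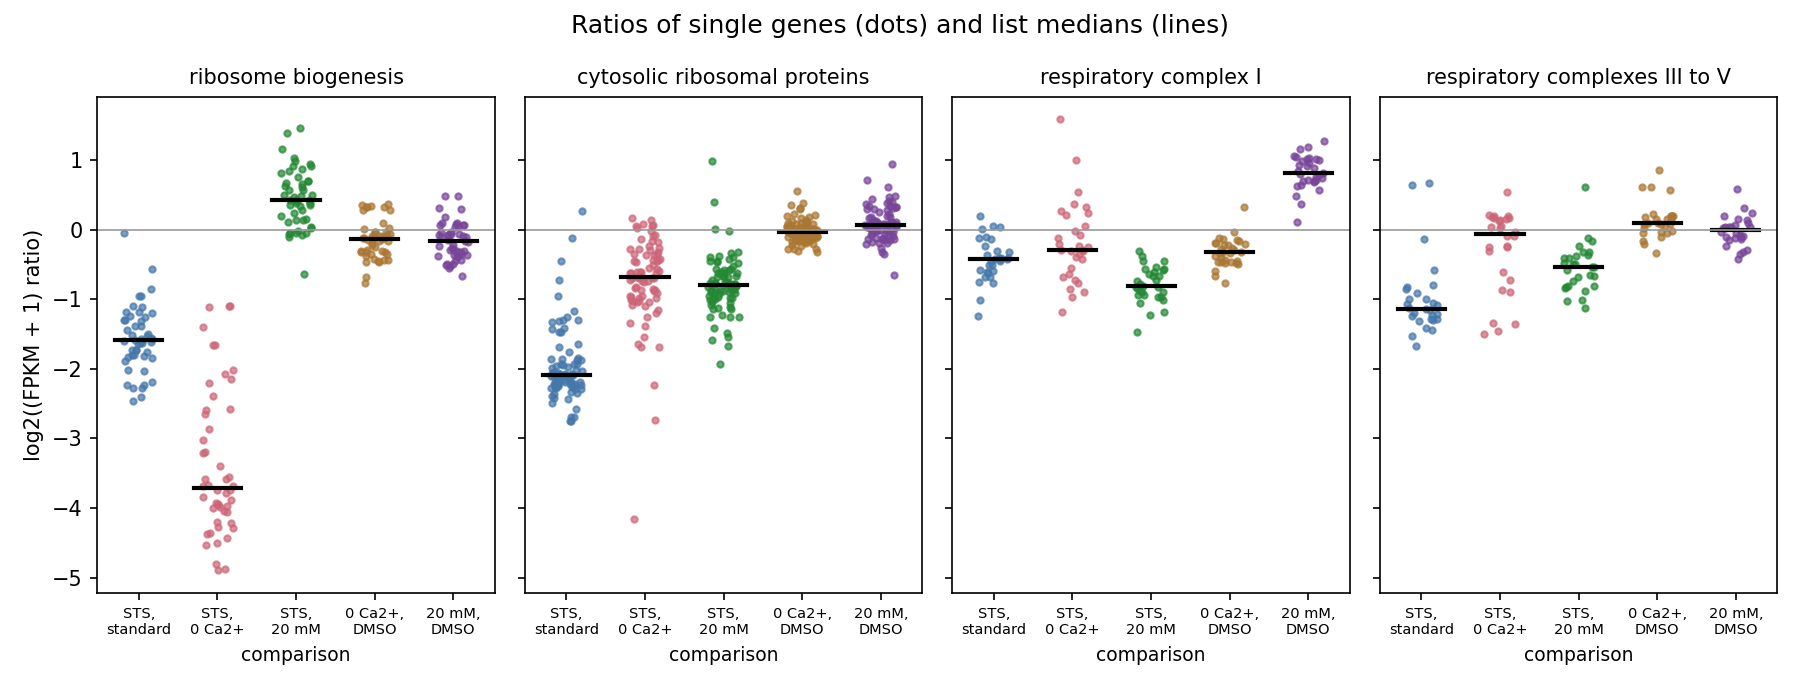
Log2((FPKM + 1) ratio) of single genes (dots, spread sideways for legibility) in 4 gene lists for staurosporine (STS) against DMSO in 3 media and for the 0 Ca2+ and 20 mM CaCl2 media against standard medium with DMSO; black lines are list medians. Complex I genes had a median of 0.80 in 20 mM CaCl2 against standard medium, and complexes III to V one of -0.01.

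The comparisons with DMSO alone address how the media differed without the drug. In 0 Ca2+ against standard medium, phosphate transporter genes were among the highest and cell wall genes among the lowest. The high-affinity phosphate transporter genes pho-5 and pho-4 went from 3.66 to 62.4 FPKM and from 24.1 to 166, pho-2, a repressible alkaline phosphatase gene, from 0.925 to 3.26, and 4 of 11 phosphate acquisition genes were higher by at least 2 times and 0 lower. The sulfate permease gene cys-14 went from 51.3 to 199 FPKM, the taurine dioxygenase genes NCU01057 and NCU07610 from 1.70 to 18.4 and from 1.06 to 11.7, the chromate ion transporter gene NCU01055 from 1.68 to 15.3 and the methionine permease gene NCU04942 from 36.6 to 202. The glutamate dehydrogenase gene gdh-1 was higher at a log2 ratio of 3.08. Cell wall genes went both ways, with 4 higher and 6 lower by at least 2 times of 70. Higher were ncw-3 (2.37) and NCU00399 (PhiA, 2.33), and lower ncw-1 (-2.85), acw-10 (-2.36), gh76-5 (-2.16) and the glucanase gene NCU07523 (-2.15). The hydrophobin gene eas, of the rodlet layer of conidia, was at 18.0 FPKM in standard and 2.10 in 0 Ca2+ medium, and the median of the 9 conidia markers was 0.66. NCU01068 (BAR domain, -2.23), NCU04122 (-2.01) and the UDP-glucose 4-epimerase gene NCU05133 (from 12.8 to 2.44 FPKM) were lower, as were NCU10610 (-3.50) and NCU09712 (-3.24), both without a name.

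Of 29 calcium handling genes 2 were higher and 3 lower by at least 2 times, at a median of -0.034 and percentile 1.88 of matched random lists. The higher ones were ena-1, listed by its annotated product alone, from 35.1 to 119 FPKM, and NCU07966, a gene annotated as calcium-transporting ATPase 3, from 12.2 to 35.1. The lower ones included cax, from 12.4 to 3.80, and nca-2, from 26.7 to 9.53. Of 58 amino acid synthesis genes 52 had a ratio above 0 and 4 were higher by at least 2 times (median 0.47, percentile 100), among them cpc-1, the regulator of cross-pathway control, from 548 to 1156 FPKM. The alternative oxidase gene aod-1 went from 324 to 726 FPKM, while 30 of 31 complex I genes had ratios below 0 (median -0.33, percentile 0), none by 2 times. The size rule counted 212 of 7079 genes higher and 165 lower, and the authors' deposited table calls 143 higher and 138 lower as significant.

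With 20 mM CaCl2, pho-4 and pho-5 lay on the other side of standard medium, but the median of the phosphate acquisition list did not. FPKM of pho-4 was 24.1 in standard and 1.70 in 20 mM CaCl2 medium, that of pho-5 3.66 and 0.524, and 2 of 10 phosphate acquisition genes were lower and 0 higher by at least 2 times. Of that list 6 genes had a ratio above 0, with a median of 0.077 at percentile 50.3 of matched random lists. Its mean was -0.48 (quartiles -0.90 and 0.32), on the side of pho-4 and pho-5. The ATPase genes NCU07966 (log2 ratio -2.60), ena-1 (-1.22) and ph7 (from 6.89 to 1.79 FPKM) were lower, as were the glucan remodelling gene gel-4 (-2.94), NCU01068 (-1.86), the CCC1 gene NCU11307 (-1.72) and NCU09677 (-1.40). The dyp-type peroxidase gene NCU09210 went from 3.24 to 43.4 FPKM, its neighbour NCU09209 (galactose oxidase) from 2.18 to 16.7, the sugar transporter gene NCU07607 from 1.12 to 17.8, the potassium transporter gene hak-1 from 0.814 to 10.5, the endothiapepsin gene NCU08739 from 9.20 to 58.5 and the oxysterol binding protein gene NCU02190 from 5.14 to 31.4. Of 18 genes in the clock and light list 4 were higher and 0 lower by at least 2 times (median 0.37). This list also had 4 of 18 genes higher and 0 lower in 0 Ca2+ against standard medium (median 0.48), and the 2 comparisons share the standard DMSO library. With 20 mM CaCl2 the higher genes included al-1 (2.24) and al-2 (2.23), of carotenoid synthesis, and vvd (1.14), a blue-light photoreceptor. The conidia marker eas was at 69.7 FPKM, a log2 ratio of 1.89. Of genes without a name NCU03240 was highest (3.15) and NCU02880 lowest (-3.52).

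Of the 28 lists, complex I had the median farthest from 0 in 20 mM CaCl2 against standard medium. All 31 genes had ratios above 0 and 9 were higher by at least 2 times, with a median of 0.80 (quartiles 0.70 and 1.00), at percentile 100 of matched random lists. FPKM of nuo21.3b went from 149 to 360.2, that of nuo9.8 from 137 to 312 and that of nuo51 from 94.4 to 211. The 28 genes of complexes III to V had a median of -0.01, with 14 ratios above 0. Over all genes 151 of 7112 were higher and 57 lower by at least 2 times, and the authors' deposited table calls 92 higher and 37 lower as significant. Both calcium comparisons share the standard DMSO library, so a difference of that library would move them in the same direction.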

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

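All tests in this part were chosen after the result was seen. Apart from complex I, the results here stood out because a list or gene went one way with staurosporine in 1 medium and the other way in another. Complex I stands here for its medians with DMSO. Its staurosporine medians were below 0 in standard, 0 Ca2+ and 20 mM CaCl2 medium (-0.42, -0.29 and -0.81). With 1 library per group none of these differences between media was tested. Part of each can lie in the DMSO libraries, as for gdh-1, with a log2 ratio of 3.08 in 0 Ca2+ against standard medium with DMSO.

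Ribosome biogenesis genes had a median log2 ratio of 0.43 with staurosporine in 20 mM CaCl2 medium, against -1.59 in standard and -3.71 in 0 Ca2+ medium. Scaling between libraries is argued against, since it shifts all genes alike, and the median difference between 20 mM CaCl2 and 0 Ca2+ medium lay 4.32 above that of the 7430 other genes (SD of those genes 1.501). So is a trend with gene length, with 4.23 after its removal (SD 1.15). A weaker drug action on every gene by 1 factor in 20 mM CaCl2 medium was set against NCU09974 and NCU09975. With a slope of 0.222 over all genes, the lower of their excesses over the predicted ratio was 3.95 (SD of genes about the line 0.569). These 2 genes lie outside the list and were already seen to be high in this medium, so their excess cannot decide the question for the list. In the list itself, 1 factor above 0 would keep the sign of each ratio. However, 42 of 50 genes lay above 0 in 20 mM CaCl2 and 0 of 50 in standard medium. A dependence of the response of these genes on external calcium may account for the pattern, as a hypothesis, and a difference between single cultures stays open without a second library.

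Complex I genes had a median of 0.80 in 20 mM CaCl2 against standard medium with DMSO and -0.33 in 0 Ca2+ medium, and -0.81 with staurosporine in 20 mM CaCl2 medium. Scaling between the libraries would move complexes III to V alike, but their median lay 0.81 lower (SD of their members 0.211). A gene length trend is argued against by a median of 0.74 with the trend removed (SD 0.248). The last value is measured against the same 20 mM CaCl2 DMSO library as the first, so 1 high library would give both. Higher transcript levels for complex I with 20 mM CaCl2 could be a response to calcium or to the salt, or a property of this 1 library, which the design leaves open.

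The ergosterol synthesis list had a median of 0.11 with staurosporine in 20 mM CaCl2 and -0.71 in 0 Ca2+ medium. The former rests on little: it turned to -0.023 with a mean FPKM of at least 10, the mean of the list was -0.00746, and 0 of 24 members were higher by at least 2 times. Higher in 0 Ca2+ and lower in 20 mM CaCl2 medium, as log2 ratios in this order, were NCU05518 (4.64 and -1.07), NCU06416 (4.38 and -2.33), its neighbour NCU06417 (2.94 and -2.35), NCU12134 (5.51 and -1.07), NCU10368 (2.21 and -2.76), NCU07607 (1.23 and -1.52), NCU02328 (3.76 and -1.34) and NCU12074 (3.16 and -1.66). Higher in 20 mM CaCl2 and lower in 0 Ca2+ medium were NCU05650 (1.10 and -5.07) and NCU01916 (1.85 and -3.99). Higher in standard and lower in 0 Ca2+ medium were gdh-1 (2.56 and -3.57), NCU05627 (1.75 and -2.91) and inv (2.30 and -2.22). Higher in 0 Ca2+ and lower in standard medium were NCU08739 (1.03 and -1.73) and NCU11307 (1.25 and -1.60).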

How the results depend on the processing

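The removal of the gene length trend and, for the gene lists, the settings without a filter or with the authors' testable genes alone were chosen after the data were seen. Of the counts that answer a comparison, 169 values under alternatives lay within 1.5 times the reported count and 58 did not. Of single genes and list medians, 2648 values stayed on the same side of the threshold or within 1 SD of the list, 67 were no longer past the threshold, 37 moved by more than that SD and 10 reversed, counting reversals only for medians in the outer 2.5% at either end of the random lists. Of medians between these ends, a further 138 values changed sign, 43 of them with equal FPKM sums. Read depth is unknown, so the precision of low FPKM values cannot be given. A minimum FPKM of 10 lowers counts because fewer genes are counted.

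Of the 6 higher and 6 lower genes in limma's test over the media, 0 and 0 passed with pseudocount 5, 0 and 0 with no filter, 0 and 0 with centred ratios, and 0 and 0 with the length trend removed, against 1047 genes at an unadjusted p below 0.05 in the fit as reported. With a pseudocount of 0.1, 1 gene was lower, and with equal FPKM sums 19 were higher. Leaving out 1 medium gave 0 to 174 higher and 0 to 362 lower, the 0 without the standard pair. Of the 4 ways to assign treatment within the pairs, the real one gave 12 genes and the highest other 0, so 1 way, the real one, gave that many. Of 10 splits of the 6 libraries without pairing, the real one gave 13 and the highest other 0, again 1 split, the real one. Both sets of splits are too few for a share under 0.05. With an estimated correlation 0 lists passed in place of 9. The fit without pairing by medium called 7 higher and 6 lower.

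With pseudocount 5, higher and lower genes for staurosporine numbered 92 and 265 in 20 mM CaCl2 medium, and 497 were higher in standard and 788 in 0 Ca2+ medium; for 0 Ca2+ against standard medium with DMSO 82 and 89, and for 20 mM CaCl2 57 and 25. Differences between the staurosporine effects gave 725 and 981 for 0 Ca2+ minus standard medium and 627 lower for 20 mM CaCl2 minus standard medium. Pseudocount 0.1 gave 295 higher with staurosporine in 20 mM CaCl2 medium, 325 in 0 Ca2+ and 257 in 20 mM CaCl2 against standard medium. With a mean FPKM of at least 10, staurosporine gave 556, 703 and 103 higher in standard, 0 Ca2+ and 20 mM CaCl2 medium, the 0 Ca2+ comparison 121 and 90, and the 20 mM CaCl2 comparison 77 and 31. The differences then gave 570 higher for 0 Ca2+ minus standard, 668 lower for 20 mM CaCl2 minus standard and 936 lower for 20 mM CaCl2 minus 0 Ca2+ medium. Centring gave 393 and 230 for staurosporine in 20 mM CaCl2 medium and 752 lower for its difference from standard medium. Equal FPKM sums gave 3500 and 367 in standard, 2212 and 1041 in 0 Ca2+ and 940 and 124 in 20 mM CaCl2 medium, and 2653 and 2044 lower for the differences from standard medium. With the length trend removed staurosporine in 20 mM CaCl2 medium gave 284 and 210, its difference from standard medium 705 lower, and 20 mM CaCl2 against standard medium 100 higher; 7 lists in place of 11 lay in the outer 2.5% at either end of the random lists for staurosporine in standard medium and 6 in place of 11 for 0 Ca2+ minus standard medium.

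Medians in the outer 2.5% that reversed were nitrogen use with staurosporine in standard medium (0.15 with equal sums), and in 20 mM CaCl2 medium ABC transporters (-0.0034 with FPKM of at least 10), ergosterol synthesis (-0.023, same setting) and autophagy (0.028, equal sums). With DMSO, cell wall genes in 0 Ca2+ medium came to 0.031 with no filter, and in 20 mM CaCl2 medium iron genes to -0.12 and sexual development genes to -0.023 with FPKM of at least 10. For 0 Ca2+ minus standard medium antioxidant genes came to -0.10 and complex I to -0.29 with equal sums, and complex I to -0.10 with the length trend removed. Apart from the smaller number of genes noted above, the cause was not tested.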

Other observations

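The tests of neighbouring genes in this part were chosen after the result was seen. With staurosporine in 20 mM CaCl2 medium, 31 of 37 antioxidant genes had a ratio below 0 and 5 were lower and 2 higher by at least 2 times, with a median of -0.73 at percentile 0 of matched random lists and -0.15 with equal FPKM sums. In standard and 0 Ca2+ medium their medians were -0.10 and 0.071, at percentiles 51.8 and 96.2. Among these genes, the catalase genes cat-1 and cat-3 went opposite ways with staurosporine. FPKM of cat-1, the catalase abundant in conidia, went from 2.88 to 37.4 in standard, from 10.6 to 69.1 in 0 Ca2+ and from 2.55 to 11.2 in 20 mM CaCl2 medium, a mean log2 ratio of 2.56 (SE 0.41), while cat-3, the catalase of growing hyphae, had -2.74 (SE 0.41). Adjusted over the list alone 1 of 38 antioxidant genes rose and 1 fell, and 0 passed in limma's test over all genes, where 1047 genes had an unadjusted p below 0.05. The alternative oxidase gene aod-1 fell when adjusted over its list alone, with -3.31 (SE 0.60), as did the plasma membrane iron permease gene NCU03497 with -2.10 (SE 0.36) and the oxysterol binding protein gene NCU02190 with -1.83 (SE 0.36). NCU02190 stands in the ergosterol synthesis list by its product name. In each of these lists 0 genes passed over all genes, and no adjustment was made over the number of lists. The blue-light-inducible gene bli-3 went from 11.4 to 155 FPKM in standard and from 32.3 to 339.8 in 0 Ca2+ medium, and was at 9.32 and 13.9 in 20 mM CaCl2 medium.

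With staurosporine, the 10 autophagy genes had medians of 0.57 in standard and 0.63 in 0 Ca2+ medium, where 4 and 4 were higher by at least 2 times. In 20 mM CaCl2 medium the median was -0.51, at percentile 2.12, with 0 genes lower by at least 2 times, and 0.028 with equal FPKM sums. The list did not pass the camera test (adjusted p = 0.107). FPKM of atg-8, which marks autophagosomes, went from 172 to 413, from 235 to 457 and from 187 to 108 in these media. Proteasome genes had medians of 0.44, 0.26 and -0.45 over 33 genes, with 1, 1 and 0 higher by at least 2 times and none lower. The medians in standard and 0 Ca2+ medium lay at percentiles 99.98 and 99.96 of matched random lists. The median in 20 mM CaCl2 medium lay at percentile 26.6 and turned to 0.13 with equal sums. For the proteasome genes the differences of 20 mM CaCl2 medium from standard and from 0 Ca2+ medium (medians -0.94 and -0.70) both lay at percentile 0. The mean and the camera direction of a list did not always share the sign of its median over the media: phosphate acquisition had a median of 0.31 and a mean of -0.0039, and histone and replication genes a median of -0.05 with a camera direction above other genes.

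Several of the named genes are neighbours, which was noted after their values were seen. NCU09974 and NCU09975 lie next to NCU09976 (0.111 to 8.31 FPKM in standard medium), NCU09140 lies next to mig-9, NCU09209 next to NCU09210, and the pyrimidine salvage genes NCU06416 and NCU06417 next to each other. That neighbouring genes respond alike to staurosporine is a hypothesis that fits the ratios: over 5394 adjacent pairs Spearman's rho of the mean log2 ratio was 0.157, above the highest of 1000 shuffles among genes of similar level (0.0732). This rho is across genes, which are not independent replicates. Reads running on from a strong gene into a weak neighbour could give the same picture. Against this as the whole cause, over the 1714 pairs whose highest FPKM of the 6 libraries lay less than 2 times apart rho was 0.223, with at most 0.138 in shuffles that chose such pairs again. For the other pairs it stays open, NCU09975 and NCU09976 among them. Dropped were 2 earlier forms of these tests: unrestricted shuffles, and pairs matched on DMSO level, which keep genes that are strong only with staurosporine. The strand of the genes was not used, so shared promoters, overlapping transcripts and local chromatin stay open.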
